A study of Mus musculus with 6 samples.

How the data were processed

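Total RNA from the tumour stroma of 6 male mice, 3 wild-type (WT) and 3 Pdia4 -/- (KO), was extracted with Trizol and labelled as biotinylated cRNA, per the labels' protocols. It was hybridised to 1 Affymetrix Mouse430_2 array per mouse, per the file headers. Each array file deposited by the authors gives, for each of 45101 probe sets, a linear signal intensity and a detection call of Present, Marginal or Absent. Per the expression report deposited for 1 array, the signals came from the Statistical algorithm of the array software with a target value of 500, and the calls used alpha1 0.05, alpha2 0.065 and tau 0.015. The mean intensity of the deposited signals after trimming was 500 on every array, so each array had been scaled by a factor of its own. The software version is not given in the sources used here. The authors' value table held the same values as the array files in 270606 of 270606 cells. The authors also deposited a table of 1554 probe sets with a signed fold, exported from a pathway analysis program per the file headers. How those folds were made and selected is not given in the sources used here.

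The plan named background correction with quantile normalization for unscaled scanner values and the log2 of the values as given for values already normalized. The deposited signals were taken as already normalized once their scale had been examined, and their log2 was tested. The 64 control probe sets were left out, and a probe set was tested if it was Present on at least 3 of the 6 arrays, which left 22063 probe sets. A pseudocount was not added. The platform annotation gave 34958 probe sets a single gene symbol, 932 several and 9211 none. Symbols were checked through Entrez IDs against a reference gene table of the assembly GRCm38.p6, where 34754 matched and 0 symbols changed. The tested probe sets with a single symbol covered 11357 genes. No genome build is named in the files, so no coordinates are given.

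WT and KO arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets. A gene was called at an adjusted p under 0.05. All tests were two-sided. Single values were also compared with an exact permutation test, whose smallest possible p for 3 arrays against 3 is 0.1. Values are mean signal ± SD over n = 3 arrays, and log2 differences are KO minus WT with the standard error (SE) from limma. Where a probe set was Present on 0 of the 3 arrays of the lower group, the fold is given as "at least", against the higher of each array's lowest Present signal and the probe set's own. These bounds are taken from means of log2 signals, equal the fitted fold where the probe set's own signal was the higher on each array, and can exceed the ratio of the printed mean signals. The labels do not say that the mice were littermates or processed separately, so p-values measure the spread between these samples. Arrays carry no read depth, and their number limits the precision.

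The gene lists, the processing plan for each kind of file and the rule for naming genes were fixed before the data were examined. There were 32 lists of pathway genes or cell type markers, and the 28 with at least 5 measured genes were tested with camera (preset correlation 0.01) on 1 probe set per gene, the tested probe set with the highest mean over the 6 arrays, with Benjamini-Hochberg adjustment over lists. camera with an estimated correlation and fry were run beside it. Named genes are Pdia4, the called genes, up to 12 genes per direction filled by the smallest p among genes with non-overlapping groups, a log2 difference of at least 1 and Present calls on the higher group, the up to 4 called members of each list or else its 3 members of smallest p, and the 3 largest folds per direction in the authors' table. Genes named outside this rule are said to be so. On simulated data of 22063 probe sets with 200 changed, limma recovered 0% of changes of 1 log2 unit, 61.2% of changes of 2 and 86.5% of changes of 3. The simulated probe sets were independent, and in the data an estimated 65.6% were unchanged, a far smaller share. These rates of recovery therefore do not carry over to the data. In simulated comparisons of 11357 genes drawn independently of each other, camera called 133 of 140 lists shifted by 1 log2 unit and 3 of 60 unshifted lists. In the data the estimated correlation within a list reached 0.96 (B cell list), so this rate of false calls does not carry over.

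The file header of KO replicate 3 carries another batch number than those of the other 5 arrays. As the sole array of its batch it allows no block, and results were recomputed without it. The alternatives were 75th percentile scaling, cyclic loess, the value table, no filter, Present on all 6 arrays, the replicate number as a block, array weights, eBayes with trend and robust, the mean of a gene's probe sets, a fold rule and leaving out each array. Alternatives chosen after seeing the data were quantile normalization of these already scaled signals, division by the β-actin 5' control, an offset of 16, leaving out 2 pairs of arrays and looser thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.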

Results

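RNA was measured in the stroma of tumours grown under the skin of 6 male B6 mice, 3 WT and 3 KO, 4 weeks after inoculation. Pdia4 encodes a protein disulphide isomerase of the endoplasmic reticulum (ER), an enzyme that forms and rearranges disulphide bonds in proteins as they fold. The growth protocol names LLC, the Lewis lung carcinoma line, whereas the series design names a GK1 tumour, and the sources used here do not settle which is meant. The series title asks which pathways lie downstream of Pdia4 in stromal cells. Between 21202 and 22185 probe sets were Present per array (47.0% to 49.2%). KO replicate 3, the array with another batch number, stood apart from the other 5. Its score on the first principal component, which held 50.6% of the variance, was 105, and the WT arrays lay at -51.0 to -37.1. KO replicates 1 and 2 lay between, the lower of them, KO replicate 1, at 11.8. Each KO array thus scored above each WT array, so this component also separated the groups. Probe sets are not independent. Across them, the log2 signals of KO replicate 3 correlated with those of the other arrays at r = 0.889 to 0.946.

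Pdia4 mRNA was lower in KO stroma but present on every array. Its brighter probe set gave 3604 ± 730 in WT and 1749 ± 502 in KO (SD, n = 3), so that KO held 48.5% of the WT signal. The log2 difference was -1.06 (SE 0.28), each KO array lay below each WT array, and limma's adjusted p was 0.161. The exact permutation p was 0.1, the smallest possible. The other Pdia4 probe set was Present on too few arrays to be tested, and read 28.3 ± 14.4 in WT and 36.9 ± 25.0 in KO (SD, n = 3). The position of either probe set relative to the deleted part of the gene is not given in the sources used here, and the tumour cells' own genotype is not labelled, so this signal does not check the labels fully.

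Ifng, the cytokine interferon gamma of T and NK cells, rose from 68.1 ± 19.8 in WT to 498 ± 50.4 in KO stroma (SD, n = 3), a log2 difference of 2.91 (SE 0.27). Klrc1, an inhibitory receptor of NK and CD8 T cells, rose from 273 ± 18.8 to 989 ± 34.6, and Cxcr6, a chemokine receptor of activated T cells, from 69.6 ± 5.35 to 259 ± 12.6. Col12a1, a fibril-associated collagen chain, rose from 102 ± 6.70 to 374 ± 13.1. Cxcr6 and Col12a1 were each Present on 1 of the 3 WT arrays, and Ifng on 2. Alox15, a lipoxygenase that oxidises arachidonic acid, fell from 104.5 ± 21.3 to 15.7 ± 3.37, at least 6.69-fold by means of log2 signals. limma's adjusted p was 0.0479 for each of these 5 genes. A probe set of Mtrex, an RNA helicase that works with the nuclear exosome, rose at least 14.7-fold (adjusted p = 0.0219), but the other tested Mtrex probe set had a log2 difference of -0.64. These 5 genes that rose and 1 that fell were all that passed among 22063 probe sets, while 2205 were higher and 2249 lower in KO at an unadjusted p under 0.05, where chance gives 1103 in all. In 30.6% of probe sets the groups did not overlap, against 10% by chance.

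The calls sat close to the threshold. limma called 0 genes without a filter (2919 probe sets higher and 1859 lower at an unadjusted p under 0.05), 0 with Present calls required on all 6 arrays (1823 and 2038) and 0 after quantile normalization (2239 and 2206). Leaving out WT replicate 2 gave 2 calls, and leaving out any other array gave 0. The split of calls also moved with the scaling, from 5 higher and 1 lower to 1 and 0 with 75th percentile scaling and to 61 and 803 after division by the β-actin 5' control, which moved the median of all probe sets by -0.65.

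**Figure D1:**
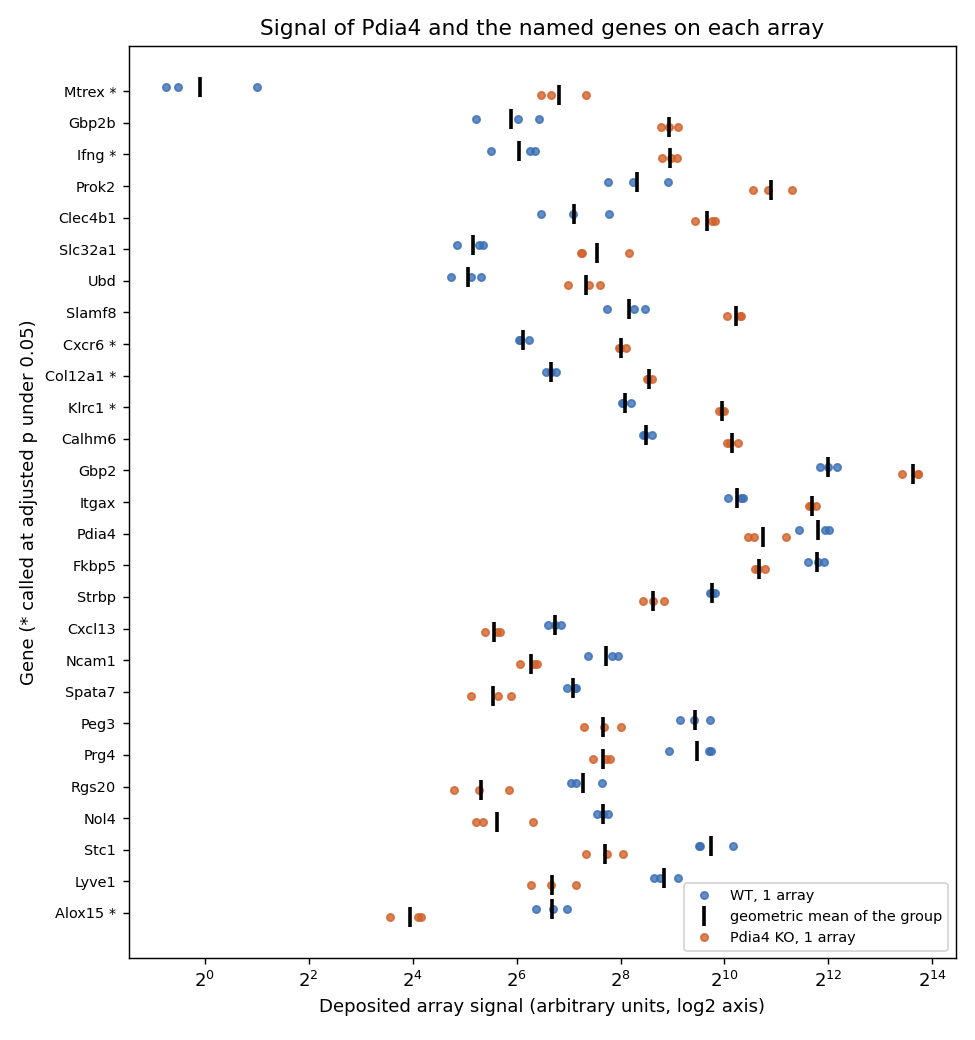
Deposited array signal (log2 axis, arbitrary units) of Pdia4 and the named genes; each point is 1 array, WT in blue and KO in orange, and bars are geometric means of 3 arrays. Starred genes passed the test, such as Ifng with 45.4 to 82.3 in WT and 445.7 to 546.1 in KO.

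Further genes with large differences are given as values, since none passed over all genes. The interferon-inducible GTPase Gbp2b was at least 8.23-fold higher in KO by means of log2 signals (limma adjusted p = 0.0655). Gbp2, another such GTPase, went from 4106 ± 464 in WT to 12647 ± 1486 in KO (limma adjusted p = 0.107). The log2 differences of Ubd, a ubiquitin-like modifier, Calhm6, an ion channel subunit, and Slamf8, a myeloid surface receptor, were 2.28, 1.64 and 2.06. Clec4b1, a lectin of dendritic cells and macrophages, and Prok2, a secreted peptide made by neutrophils, differed by 2.56 and 2.58, and Itgax, the CD11c integrin, by 1.44. Slc32a1, a vesicular GABA transporter, was at least 5.24-fold higher. On the other side, Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, had 460 ± 78.4 in WT and 106 ± 32.0 in KO (SD, n = 3; adjusted p = 0.107). Stc1, a secreted glycoprotein, Peg3, an imprinted zinc finger gene, Prg4, lubricin, and Ncam1, a cell adhesion molecule, had log2 differences of -2.04, -1.76, -1.80 and -1.45.

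Other genes lower in KO were Nol4, at least 4.07-fold, and Spata7, at least 2.88-fold. Cxcl13, a B cell chemokine, had -1.16 and Fkbp5, a glucocorticoid-induced co-chaperone, -1.10. Probe sets disagreed for 2 genes. Rgs20, a regulator of G protein signalling, had -1.97 against 0.33 on its other probe set, and Strbp, an RNA-binding protein, had -1.13 against a range of -1.18 to 1.20 on 4 others. The adjusted p of these genes was 0.13.

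As sets of genes, 18 lists were shifted up in KO and 1 down among the 28 tested. In 17 of the 18, each KO array's list mean lay above each WT array's, and the exception was the neutrophil list. Chance separates 3 arrays from 3, in either direction, in 10%, and 30.6% of all tested probe sets did so here. As the 18 lists were called as higher on the same arrays, neither share is a fair reference for them. None of the 19 calls held with an estimated correlation, where the smallest adjusted p was 0.214. fry, which asks whether a list's own genes move one way on balance, called 10 lists, 8 of them also called by camera, with a smallest adjusted p of 0.0212. Of camera's calls, fry did not call the M1-type, M2-type, macrophage, neutrophil, T cell and endothelial lists (fry adjusted p = 0.062 to 0.151). Nor did it call the chemokine, STAT3, matrix remodelling, proliferation and immediate early lists (fry adjusted p = 0.062 to 0.334). Without KO replicate 3 the shift, a list's mean minus that of all other genes, moved by over 1.5 times in 8 of the called lists. Other divisions of the 6 arrays into 3 and 3, which keep part of any difference between the genotypes, called up to 17 lists. Lists share members, and counts adjusted over all genes were 0 in every list except the NK list. The KO arrays also had 3' to 5' ratios of the β-actin controls of 1.51 to 1.99, against an overlapping 1.66 to 4.26 in WT.

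T cell and cytotoxic transcripts were higher in KO. Of 12 measured T cell markers 10 were higher, with a mean log2 difference of 1.11, and 7 passed when adjusted over the list alone against 0 over all genes. The CD8 coreceptor chains led, with Cd8b1 at 252 ± 179 in WT, with 458 on WT replicate 3, and 1307 ± 277 in KO and Cd8a at 239.5 ± 161 and 1022 ± 103 (SD, n = 3), followed by Cd3g, a T cell receptor subunit, at 604 ± 235 and 1448 ± 70.0. The list was shifted up by camera (adjusted p = 7.35e-06; adjusted p = 0.252 with an estimated correlation). Of 15 NK and cytotoxic markers 13 were higher, 8 of them adjusted over the list alone and 1, Ifng, over all genes (adjusted p = 2.62e-07 by camera; adjusted p = 0.214 with an estimated correlation).

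Inflammatory macrophage genes had a mean log2 difference of 1.65, the largest of the 28 tested lists, but 1.12 without KO replicate 3, where the neutrophil list had 1.46. All 16 measured members of the M1-type list were higher and 12 passed adjusted over the list alone, 0 over all genes (camera adjusted p = 4.06e-10; adjusted p = 0.227 with an estimated correlation). Cxcl9, an interferon-induced T cell chemokine, had 1301 ± 486 in WT and 6300 ± 930 in KO, Il1b, the cytokine interleukin 1 beta, 9700 ± 155 and 33457 ± 17868, and Irf1, an interferon-induced transcription factor, 2365 ± 223 and 7139 ± 3243 (SD, n = 3). Of 18 M2-type genes 14 were higher, 3 adjusted over the list alone and 0 over all genes, with Il4ra, the interleukin 4 receptor, at 0.88, Il10, an anti-inflammatory cytokine, at 3.12 (2.06 without KO replicate 3) and Pparg, a lipid-sensing receptor, at 1.06 on the log2 scale (camera adjusted p = 4.92e-04; adjusted p = 0.284 with an estimated correlation). Of 18 general macrophage markers 15 were higher with a mean of 0.48. By limma 0 passed adjusted over the list alone and 7 were higher at an unadjusted p under 0.05, and Itgam, Aif1 and Cd68 had 1.24, 1.11 and 0.74 (camera adjusted p = 6.08e-05; adjusted p = 0.302 with an estimated correlation). Without KO replicate 3 the shift went from 1.72 to 0.97 for the M1-type list, from 0.70 to 0.34 for the M2-type list and from 0.54 to 0.32 for the macrophage markers.

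Interferon-response and antigen-presentation genes were higher in KO with few exceptions. In the interferon list 21 of 22 genes were higher, with 5 adjusted over the list alone and 0 over all genes, and Gbp2, Zbp1, a nucleic acid sensor, and Gbp3, a GTPase, had log2 differences of 1.62, 1.54 and 1.36 (camera adjusted p = 1.57e-08; adjusted p = 0.214 with an estimated correlation). In the antigen-presentation list 18 of 19 were higher, 11 adjusted over the list alone and 0 over all genes, led by the immunoproteasome subunit Psmb9 (1.24) and the MHC class II chains H2-Ab1 (1.10) and H2-Eb1 (1.15), with camera adjusted p = 1.03e-08 and adjusted p = 0.214 with an estimated correlation. Among 25 chemokines 22 were higher, 15 up and 2 down adjusted over the list alone and 0 over all genes. Cxcl9 had 2.34 and Ppbp, a platelet and neutrophil chemokine, 1.80, whereas Cxcl13 had -1.16 (camera adjusted p = 5.20e-09; adjusted p = 0.214 with an estimated correlation). Of 11 checkpoint genes 8 were higher, 5 adjusted over the list alone and 0 over all genes, including Cd274, the PD-L1 ligand, at 941 ± 19.0 and 4867 ± 3090, with 8434 on KO replicate 3, Pdcd1, its receptor PD-1, at 103 ± 30.2 and 298 ± 80.5, and Sirpa, the CD47 receptor, at 0.92 (camera adjusted p = 4.82e-04; adjusted p = 0.214 with an estimated correlation).

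Neutrophil genes were higher too, all 11 measured, with 4 adjusted over the list alone, 0 over all genes. Csf3r, the receptor for the growth factor G-CSF, Fpr2, a formyl peptide receptor, and Mmp8, a neutrophil collagenase, had 1.42, 1.92 and 1.38 (camera adjusted p = 3.74e-05; adjusted p = 0.284 with an estimated correlation). This list's array means overlapped between the groups. Its member Ngp, a granule protein, read 51535 on WT replicate 3 and 40685 on KO replicate 2, against 1055 to 19159 on the other 4 arrays. The list's shift, 1.57, was 0.97 without WT replicate 2. It was 2.49 without WT replicate 3, a setting that keeps KO replicate 2. In the mast cell list 9 of 10 were higher, 3 adjusted over the list alone and 0 over all genes, led by Hdc, which makes histamine, with 1.45, and the proteases Tpsab1 and Mcpt4 with 1.18 and 0.80 (camera adjusted p = 0.00259; adjusted p = 0.214 with an estimated correlation). Dendritic cell markers were not called by camera (adjusted p = 0.135) but were by fry (adjusted p = 0.047). Of 9 measured 5 were higher and 4 lower, with a median log2 difference of 0.16. Itgax, Batf3, a dendritic cell transcription factor, and Cd83, a maturation marker, had 1.44, 0.91 and 1.87 (Cd83 1.12 without KO replicate 3). Adjusted over the list alone 3 up and 1 down passed, 0 over all genes. camera called the list with Present calls on all 6 arrays (adjusted p = 0.0446, range over the alternatives 0.0446 to 0.387).

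Of 32 STAT3 pathway genes 24 were higher, 1 adjusted over the list alone and 0 over all genes. Pim1, a kinase, Lrg1, a secreted glycoprotein, and Il10 had 2.12, 1.83 and 3.12, the last 2.06 without KO replicate 3 (camera adjusted p = 1.84e-04; adjusted p = 0.214 with an estimated correlation). In the immediate early and heat shock list 16 of 20 were higher, with 3 up and 1 down adjusted over the list alone and 0 over all genes. Its members parted, as the early response factors Nr4a1 and Egr1 had 1.43 and 1.27 while the chaperone Hsph1 had -1.49 (camera adjusted p = 8.51e-04; adjusted p = 0.302 with an estimated correlation). Redox genes were higher in 15 of 23, 2 adjusted over the list alone and 0 over all genes. They were led by Slc7a11, a cystine importer, with 2.54, Hmox1, haem oxygenase, with 1.03, and Gsr, glutathione reductase, with 0.99 (camera adjusted p = 0.00139; adjusted p = 0.214 with an estimated correlation). Of 22 apoptosis genes 17 were higher, 0 by limma adjusted over the list alone and 4 at an unadjusted p under 0.05, with the death ligand Fasl, the death-promoting gene Pmaip1 and the ligand Tnfsf10 at 0.82, 1.02 and 0.51 (camera adjusted p = 0.00689; adjusted p = 0.214 with an estimated correlation). After division by the β-actin 5' control Tnfsf10 read -0.15. Without KO replicate 3 the shift went from 0.68 to 0.32 for the immediate early and heat shock list and from 0.35 to 0.23 for the apoptosis list.

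Matrix genes went both ways. Of 24 in the remodelling list 16 were higher, 7 up and 3 down adjusted over the list alone and 0 over all genes. Mmp13, a collagenase, had 1287 ± 200 in WT and 14622 ± 12152 in KO (log2 difference 3.21, and 2.57 without KO replicate 3) and Postn, periostin, 366 ± 53.3 and 795 ± 174, whereas Adamts1, a metalloprotease, had a log2 difference of -1.29 (camera adjusted p = 0.0113; adjusted p = 0.302 with an estimated correlation). That call was lost without WT replicate 1 and KO replicate 3 (adjusted p = 0.0746, range over the alternatives 3.83e-04 to 0.0746), and without KO replicate 3 alone the shift went from 0.46 to 0.30. The fibroblast list was not shifted (camera adjusted p = 0.62), with 4 up and 3 down adjusted over the list alone. Postn and Col1a1, a collagen I chain, had 1.11 and 1.70 and Dpt, dermatopontin, -0.94. Its median log2 difference was -0.12, its mean 0.08 and its test direction up.

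Endothelial markers were higher in 12 of 13, with 0 by limma adjusted over the list alone and 5 at an unadjusted p under 0.05. Pecam1, an adhesion molecule, was at least 3.69-fold higher, Sox18, a transcription factor, at least 2.51-fold and Cldn5, a tight junction protein, had 1.20 (camera adjusted p = 4.05e-04; adjusted p = 0.214 with an estimated correlation). Without KO replicate 3 the list's shift went from 0.79 to 0.41. Of pericyte markers, Rgs5 had -1.21, the 1 of 5 that passed adjusted over the list alone, and Mcam and Acta2 had 0.69 and 0.39 (camera adjusted p = 0.731), Acta2 turning to -0.27 after division by the β-actin 5' control. The angiogenesis list was not shifted (camera adjusted p = 0.942; 0 by limma adjusted over the list alone, 3 higher and 4 lower at an unadjusted p under 0.05), with Thbs1, thrombospondin 1, at 1.71 and the growth factors Vegfc and Pgf at -1.16 and -0.78. Its median and mean were -0.18 and -0.06, but its mean against all other genes was 0.0052, while its test pointed down. Of 14 adipocyte markers 6 were measured. All 6 were higher, 1 adjusted over the list alone and 0 over all genes, with Pparg, Dgat2 and Acvr1c at 1.06, 0.93 and 1.82 (camera adjusted p = 5.74e-04; adjusted p = 0.214 with an estimated correlation). The adipocyte and endothelial lists were dim, with array means of 6.65 to 8.06 and 6.28 to 7.55 (mean log2 signal). The median tested probe set lay at 8.56 to 8.81 on the 6 arrays.

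Cell-division genes were lower in KO on average, with overlapping arrays, and the keratins Krt18 and Krt8 were lower on each KO array than on any WT array. Of 30 proliferation genes 29 were lower, with a mean log2 difference of -0.73, 0 passed by limma adjusted over the list alone and 2 were lower at an unadjusted p under 0.05. Mcm6, a replication helicase subunit, Cenpf, a kinetochore protein, and Ccna2, cyclin A2, had -1.14, -1.11 and -1.12 (camera adjusted p = 8.51e-04; adjusted p = 0.602 with an estimated correlation). The list means overlapped, at 10.22, 10.52 and 10.86 in WT and 9.95, 10.63 and 8.82 in KO (mean log2 signal; exact permutation p = 0.3). Without KO replicate 3 the shift went from -0.67 to -0.22 and the list was no longer called (adjusted p = 0.0568, range over the alternatives 5.95e-08 to 0.0568), and without KO replicate 2 the shift was -1.04. The simple-epithelium keratins Krt18 and Krt8 had 6726 ± 1158 and 6556 ± 1007 in WT and 1955 ± 1005 and 2203 ± 1247 in KO (SD, n = 3), and both passed adjusted over the list alone but not over all genes (limma adjusted p = 0.148 and 0.162). With 4 measured genes the epithelial list, which also held Krt7 at -0.82 (-0.15 without KO replicate 3) and Cdh1, E-cadherin, at 0.33, was not tested.

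ER and protein-folding genes gave no list call by camera, and fry called the protein disulphide isomerase family. In the protein disulphide isomerase family 12 of 17 were lower, 0 by limma adjusted over the list alone and 4 at an unadjusted p under 0.05, with Pdia6 at 11141 ± 739 in WT and 5260 ± 1581 in KO and Txndc11 and Pdia5 at -0.58 and -0.80 (camera adjusted p = 0.09; fry adjusted p = 0.047). The other Pdia6 and Txndc11 probe sets read 1.03 and 0.40. The family list was called without KO replicate 3, with or without WT replicate 1 (lowest adjusted p = 0.0485, range over the alternatives 0.0485 to 0.227). Of 28 ER stress genes 17 were lower, 0 by limma adjusted over the list alone, with 4 higher and 4 lower at an unadjusted p under 0.05. The chaperone partners Dnajc3 and Creld2 had -0.76 and -0.70 and Ppp1r15a, which ends the stress block on translation, 1.85 (camera adjusted p = 0.937). The median was -0.13, the mean 0.03 and the test direction down. The hypoxia list was not shifted (camera adjusted p = 0.798; 0 by limma adjusted over the list alone, 3 lower at an unadjusted p under 0.05), with Car9, a carbonic anhydrase, Adm, adrenomedullin, and P4ha2, a collagen hydroxylase, at -0.63, -0.84 and -1.08.

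The B cell list and the erythroid and blood list gave no call by camera or fry. The B cell list (camera adjusted p = 0.731; 0 by limma adjusted over the list alone and 0 at an unadjusted p under 0.05) was high on WT replicate 3 and KO replicate 2, where Ighm, the IgM heavy chain, read 27950 and 16791 against 352 to 1062 on the other 4 arrays. Cd79a and Pou2af1 followed it, with 400 and 349 against 22.7 to 64.6 and 2045 and 775 against 20.9 to 113.5. The list was called higher in KO without WT replicate 3, with or without KO replicate 2 (adjusted p range over the alternatives 7.24e-04 to 0.982). The erythroid and blood list (camera adjusted p = 0.136) held Ppbp at 1.80, the sole member passing adjusted over the list alone, Pf4 at 0.60 and Hba-a2 at 0.55, the last 2 turning to -0.054 and -0.10 after division by the β-actin 5' control. Untested lists of under 5 measured genes held the muscle genes Casq1, Eno3 and Mylpf at 0.75, -0.38 and -0.23 (list median -0.12, mean 0.03), the skin genes Krt10, Sbsn and Lor at -1.19, -0.16 and 0.13, where Krt10 passed adjusted over the list alone, and the nerve genes S100b, Pmp22 and Mbp at -0.76, -0.37 and -0.14. Other probe sets of Sbsn and Mbp read 0.31 and -0.99 to 0.83.

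**Figure D2:**
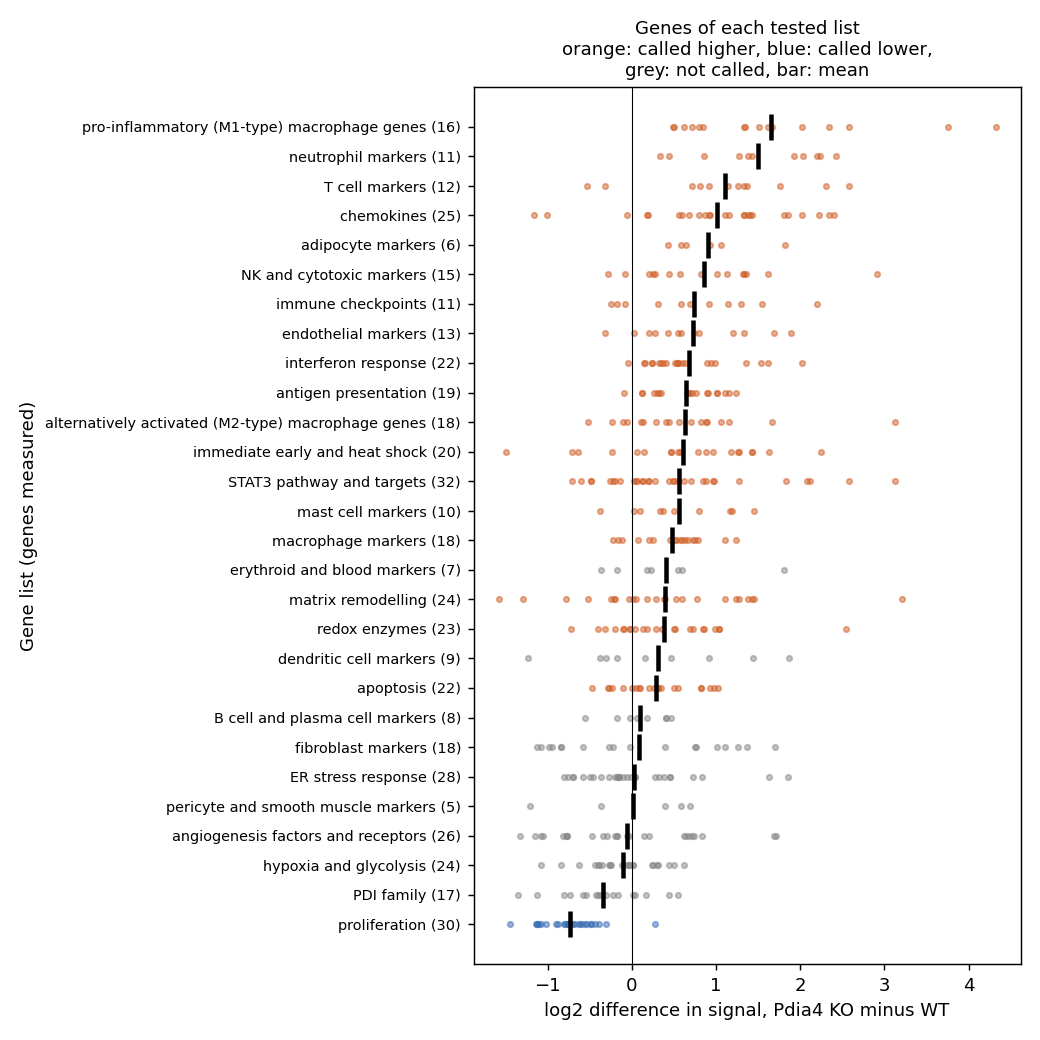
log2 difference in signal, KO minus WT, of each measured gene (points) in the 28 tested lists, with the list mean as a bar; colours mark lists called by camera with the preset correlation. The M1-type list has the highest mean, 1.65, and the proliferation list the lowest, -0.73; without KO replicate 3 these are 1.12 and -0.24, and the neutrophil list is highest at 1.46.

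The authors' deposited table held 1554 probe sets, 1488 with a positive fold, which here means higher in WT, and 66 with a negative fold. At its WT end the authors' deposited table gave 8.61 for Depp1, 8.01 for Ano1, a chloride channel, and 7.30 for Ptgis, prostacyclin synthase. Depp1 was not tested here, and the log2 differences of the other 2 were -2.50 and -2.45 (Ptgis -1.81 without KO replicate 3). At its KO end the authors' deposited table gave -26.2 for Tnf, -8.03 for Rasgef1b and -7.50 for Egr2. All 3 genes were highest by far on KO replicate 3. Tnf, a macrophage cytokine, read 290.7 to 301.3 in WT and 1282, 1486 and 32802 in KO (limma log2 difference 3.75, SE 1.13, adjusted p = 0.175). Rasgef1b read 181.3 to 319.9 in WT and 489.9, 777 and 7437 in KO, and Egr2, an early response transcription factor, 227 to 479 in WT and 678, 545 and 10916 in KO. Of the 200 genes of smallest p here 76 were in the authors' deposited table, all 76 in the same direction, on the same arrays. Of its probe sets 1206 had an unadjusted p under 0.05 here and 0 were called by limma. Each of its 1554 folds equalled the WT over KO ratio of mean signals multiplied by the KO over WT ratio of the β-actin 5' control (1.53, used unrounded), within 0.002, with ratios under 1 given as negative inverses. For Pdia4 the authors' deposited table gave 3.16, where the ratio of deposited means was 2.06.

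**Figure D3:**
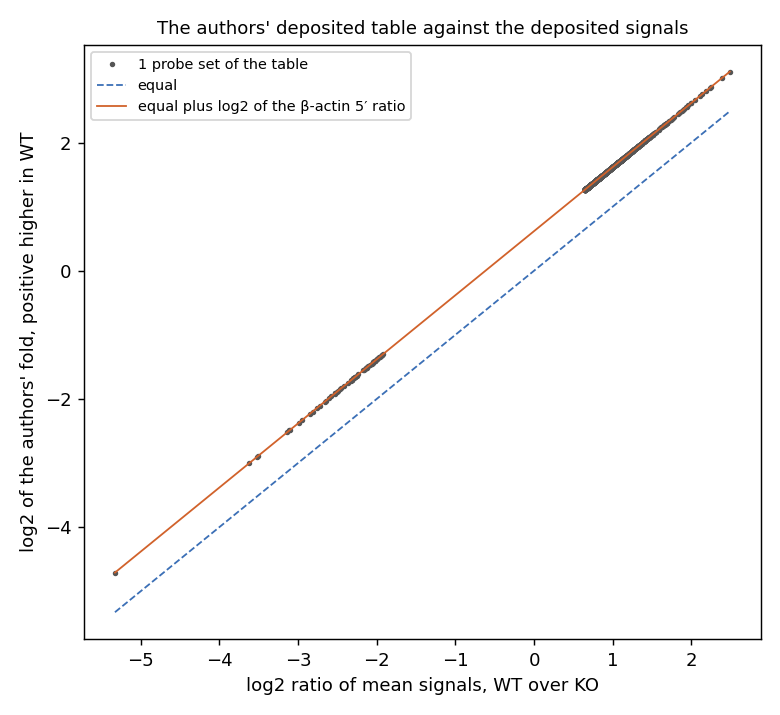
log2 of the authors' fold (vertical, positive higher in WT) against the log2 ratio of mean deposited signals, WT over KO (horizontal), for the 1554 probe sets of the authors' deposited table. The points follow the line displaced by 0.62, the log2 of the KO over WT ratio of the β-actin 5' control, and not the dashed line of equality.

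**Figure D4:**
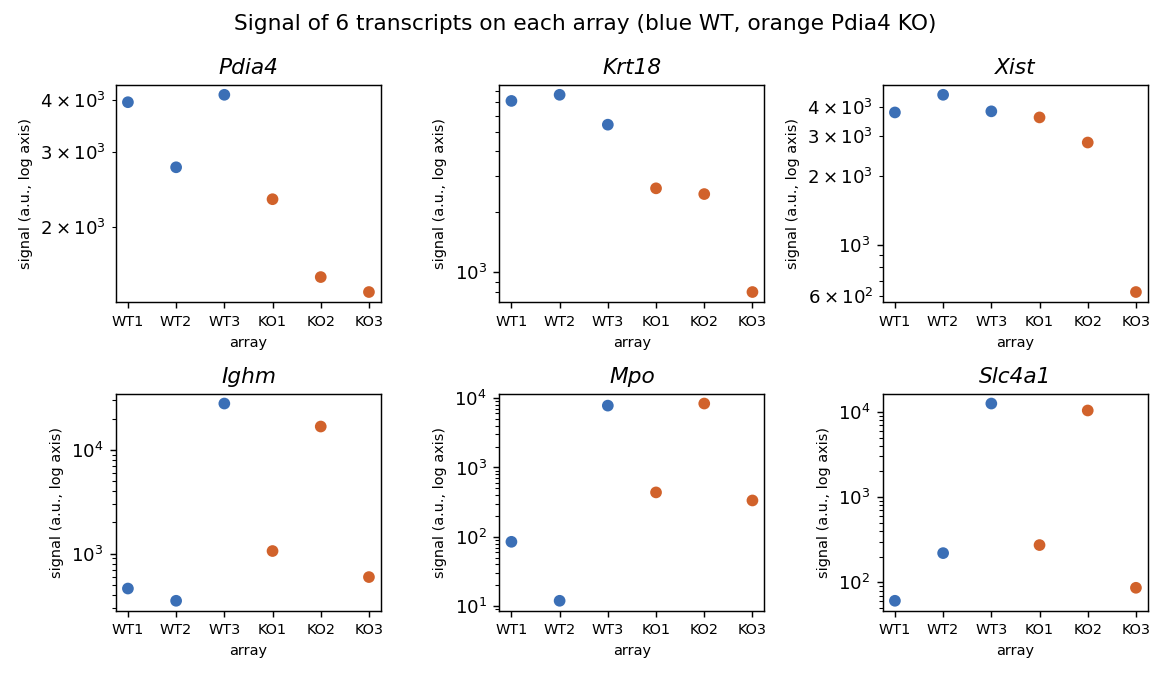
Deposited signal (log axes, arbitrary units) of 6 transcripts on each array, WT in blue and KO in orange, 1 point per array. Pdia4 and Krt18 are lower on each KO array, KO replicate 3 is lowest for Xist at 623.5, and Ighm, Mpo and Slc4a1 are high on WT replicate 3 and KO replicate 2.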

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

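The tests of the authors' deposited table given here were chosen after the result was seen, and the counts of splits were planned. The β-actin 5' control probe set, which entered no comparison, was higher on each KO array (30703 ± 6830) than on any WT array (20005 ± 6549, SD, n = 3), a KO over WT ratio of means of 1.53. It was the 1 of 16 mouse housekeeping control probe sets to separate the groups so, where chance gives 0.8. The middle and 3' controls of the same mRNA had ratios of 1.25 and 0.981, and the Gapdh 5', middle and 3' controls had 1.46, 1.22 and 0.970, with overlapping groups.

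The authors' deposited table ran 95.8% towards WT. On the deposited scale, 26.2% of the tested probe sets past the table's smallest fold were higher in WT, which argues against an excess of such transcripts on that scale. A candidate explanation is that the group means were divided by those of the β-actin 5' control, since all 1554 folds matched this within 0.002 and 0 of the 15 other housekeeping controls had a ratio in the factor's range. Whether β-actin mRNA itself was higher in KO by that factor, 0.62 on the log2 scale, stays open, since its 3' control (ratio 0.981, log2 difference -0.03, SE 0.21) lay over 2 SE below it and its middle control (0.31, SE 0.18) within 2 SE. Whether genotype or RNA integrity set the 5' signal was not tested.

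Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 6 genes and the highest other 0, and it called 19 lists and the highest other 17. In both cases 1 of the 10 splits, the real one, gave as many. Each other split still divided the genotypes unevenly, so it kept part of any difference between them and gives no null count.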

How the results depend on the processing

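Alternatives chosen after seeing the data were quantile normalization, division by the β-actin 5' control, the offset, leaving out 2 arrays together and adjusted p thresholds of 0.1 and 0.25; where no cause is given, the cause was not tested. Against 5 genes higher in Pdia4 KO than WT and 1 among genes lower in Pdia4 KO than WT, the counts were 1 and 0 with 75th percentile scaling, 0 and 0 with no filter, Present on all 6 arrays, quantile, or leaving out WT1 and KO3 or WT3 and KO2, 16 and 2 with array weights, 21 and 3 with trend and robust, 13 higher with the mean of a gene's probe sets, 10 higher with the offset, 61 and 803 after division by β-actin 5' (which moved the median by -0.65), 641 and 576 with the fold rule, 10 higher at adjusted p under 0.1 and 1534 and 1742 under 0.25. Leaving out 1 array gave 0 to 2 higher and 0 lower, with fewer samples. The replicate block gave 0 and 0. Its numbers did not pair the samples, as same-numbered arrays deviated with r = 0.157, 0.025 and -0.101, and not every array correlated best with its own number. Pdia4 passed only after division by β-actin 5' (-1.71, limma adjusted p = 0.035, range over the alternatives 0.035 to 0.448). camera called no list as shifted with an estimated correlation (0 against 19; fry called 10), and with the preset correlation its count was 18 to 20 over the other alternatives. The overlap of the top 200 genes with the authors' table went from 76 to 34 with no filter and 150 after that division. Lists that were not called changed sign. The shift of the list angiogenesis factors and receptors, 0.0052, became -0.013 with cyclic loess, -0.014 with quantile, -0.061 with no filter, -0.23 with Present on all 6 arrays, -0.034 with the offset, -0.077 without WT3 and KO2, and -0.15 to 0.085 without 1 array. The shift of the list ER stress response, 0.095, became -0.036 with no filter, -0.0021 with array weights, -0.026 without WT1 and KO3, and -0.033 to 0.18 without 1 array. The shift of the list B cell and plasma cell markers, 0.16, became -0.29 with array weights, -0.16 without WT1 and KO3, and -0.77 to 2.07 without 1 array. Without 1 array the shift of the list hypoxia and glycolysis ran from -0.15 to 0.074 and the shift of the list pericyte and smooth muscle markers from -0.0053 to 0.14. Among named genes, none called, Lor turned from 0.13 to -0.18 with array weights, -0.52 after division by β-actin 5' and -0.43 to 0.43 without 1 array, and Sbsn from -0.16 to 0.078 with the mean of probe sets and 0.11 without WT3 and KO2. Division by β-actin 5' also turned Ighm (-0.25), Pou2af1 (-0.19), Acta2 (-0.27), Hba-a2 (-0.10), Pf4 (-0.054) and Tnfsf10 (-0.15), and without 1 array Ighm ran from -1.06 to 2.45, Pou2af1 from -0.79 to 2.51 and Cd79a from -1.24 to 0.24. Of the other list values 535 kept direction and side of the threshold, 5 gained and 21 lost the call, 19 of these with the estimated correlation. Of named-gene values 2137 kept both, 70 gained and 69 lost. The value table held identical values. No background correction could be undone and the authors' information file names no plain test, so neither was run, and the batch number allowed no block. Signals near background limit Mtrex, Alox15, Gbp2b, Slc32a1, Nol4, Spata7, Pecam1 and Sox18 to bounds. Cxcr6 and Col12a1, given without a bound, were Present on 1 of the 3 WT arrays.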

Other observations

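The tests of explanations in this part were chosen after the results were seen, and the genes named here outside the lists were chosen after their values were seen. Xist, the RNA that coats the inactive X chromosome of female cells, was Present on all 6 arrays, although the mice are labelled male. Its brighter probe set read 3784, 4518 and 3827 in WT and 3600, 2798 and 623.5 in KO, and another had a log2 difference of -2.37 (SE 0.73, limma adjusted p = 0.178), which was -1.43 without KO replicate 3. The Y-linked genes Eif2s3y and Kdm5d were Present on all 6 arrays too. Eif2s3y read 783 ± 159 in WT and 1321 ± 458 in KO, and Kdm5d 335 ± 73.4 in WT and 346 ± 37.7 in KO (SD, n = 3).

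Transcripts of blood-forming cells were abundant on WT replicate 3 and KO replicate 2. Ngp, a granule protein of immature neutrophils, read 51535 and 40685 there and 1055 to 19159 on the other 4 arrays. Mpo, myeloperoxidase, read 7787 and 8341 against 12 to 437, and Slc4a1, the red cell anion exchanger, 12533 and 10391 against 60.9 to 274. The plasma cell gene Jchain read 8451 and 4044 against 47.0 to 159. Of the 4 probe sets shared by several globin genes, the 1 that was dimmest, at 3725 to 27865, was highest on both of these arrays. The others read 25557 to 58956 over the 6 arrays, and 2 of them were lowest on KO replicate 2.

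This blood cell pattern crosses the groups, so no explanation by genotype was tested, and the tests concern which tissue it came from. Of granulocyte and erythroid precursor genes in no fixed list, 10 of 10 measured (100%) were highest on both arrays, such as Prtn3, Ctsg, Klf1 and Rhag, where chance gives 6.67% and all tested probe sets gave 6.21%. That argues against lymph node tissue alone and fits blood-forming tissue, such as marrow or spleen, which may have been collected with these samples. The precursor genes mark the same cell types as Mpo and Slc4a1, which were seen first, so the chance rate is no independent check. Hba-a2 read 47.2 to 111.6 over the 6 arrays. The early B cell genes do not tell marrow from spleen, because 2 were measured and 50% were highest on both. Mature B cell genes were highest on both in 4 of 4 and T cell genes in 0 of 10, but no test of tissue was made on these sets.

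List means were also taken against that of the macrophage markers, 8 differences in all (log2, KO minus WT). The M1-type list had 1.18 (SE 0.36) and the NK list 0.38 (SE 0.14), with no overlap of the groups (exact permutation p = 0.1, the smallest possible). The groups overlapped for the T cell (0.63, SE 0.37), neutrophil (1.03, SE 1.11), endothelial (0.25, SE 0.19), antigen-presentation (0.16, SE 0.32), fibroblast (-0.40, SE 0.21) and B cell lists (-0.38, SE 2.19). Without 1 array the ranges were 0.82 to 1.38 for the M1-type, 0.31 to 0.51 for the NK, 0.41 to 0.99 for the T cell, 0.42 to 2.04 for the neutrophil, 0.14 to 0.40 for the endothelial, -0.0066 to 0.45 for the antigen-presentation, -0.51 to -0.21 for the fibroblast and -1.61 to 1.43 for the B cell list. Without WT replicate 3 the T cell, neutrophil and antigen-presentation lists did not overlap (0.99, 2.04 and 0.45), nor did the endothelial list without WT replicate 2 (0.40) or the fibroblast list without WT replicate 1 (-0.49) or KO replicate 1 (-0.51).

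The immune lists higher in KO could reflect fewer tumour cells among otherwise equal host cells, as Krt18 and Krt8 were lower. The M1-type difference of 1.18 kept the groups apart and over 2 SE from 0 without each array in turn. That argues against this as the sole cause for those genes, provided that both lists would otherwise rise alike in log2. Whether they would was not tested, and the macrophage markers were brighter. Their array means were 13.0 to 14.1, against 9.95 to 12.8 for the M1-type list (mean log2 signal). The evidence is also limited, as the exact permutation p of 0.1 is the smallest that 3 arrays against 3 can give. For T cells the mix and the share of tumour cells cannot be told apart, because the difference of 0.63 lay within 2 SE of 0 and the overlap rested on WT replicate 3, and the NK difference fell within 2 SE of 0 without WT replicate 1 (0.32, SE 0.21) or WT replicate 2 (0.31, SE 0.20). Without KO replicate 3, 18 of the 18 lists stayed called, and 17 had both other KO arrays above each WT array. Their direction therefore did not rest on that array alone. Whether it set the calls cannot be decided, as the lists were picked on these arrays. Other splits, which keep part of any difference between the genotypes, called up to 17. KO replicate 3 moved the shift of 8 called lists, the proliferation list among them, by over 1.5 times. A change with genotype in host cells, and the 3' to 5' ratios of β-actin, which overlapped between the groups, stay open and untested.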
